A study of Rattus norvegicus with 138 samples.

How the data were processed

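Raw counts of mature rat miRNAs in serum were deposited as 1 table of 471 miRNAs by 138 libraries, and every column could be matched to a sample. Per the labels' protocols, RNA quality was checked on a Bioanalyzer, libraries were made with a Norgen small RNA kit and sequencing ran on a NextSeq instrument. Per the submitters' processing notes, reads were assigned on the rat assembly Rnor_6.0, while the aligner, the counting tool and the miRBase release are not given in the sources used here. No reads were realigned. No genome coordinates were used, because the reference available here has another build than the one named by the submitters.

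The analysis ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Low counts were filtered with filterByExpr in edgeR (minimum count 10, minimum total 15), and libraries were scaled with TMM factors. Quasi-likelihood negative binomial models were fitted in edgeR with 1 mean per metal and time point. A miRNA was called at an adjusted p under 0.05 (Benjamini-Hochberg within each comparison). Each of 31 comparisons of a metal with Ta at 1 time point used the libraries of that time point only (270 miRNAs at 1 mo, 167 at 3 mo, 272 at 6 mo and 224 at 12 mo). The comparisons averaged over time points, the changes with time and the comparisons of time points used all 138 libraries in 35 groups (320 miRNAs tested). The time comparisons gave equal weight to the 8 metals sampled at all 4 time points, Ta among them, and left out Ni. CPM values are counts scaled to library size with the TMM factors, given as mean ± SD over libraries; log2 changes are given ± SE from the model. Correlations used log2 CPM with a prior count of 2.

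By the series text each group had 8 rats, bled at every time point. The labels number the samples of each group from 1 to 4 and do not say which rats these were, or whether the same ones at several times, so samples were treated as independent. Each p therefore measures the spread between samples. Intervals and floors cover counting error only: where a miRNA had no count in a whole group, a bound was set from 3 counts over that group. Fitted log2 changes of a miRNA with groups of zeros depend on the prior, so detections and CPM are given for these instead.

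The comparisons, the miRNAs to name and the alternatives were fixed before the data were examined. Named are the 4 miRNAs with the smallest p among those that rose and the 4 among those that fell in each comparison at 1 time point, 10 and 10 in each average or time comparison, any miRNA called in 3 or more comparisons with Ta, and members of a list where the list is described. Always given were miR-1-3p, miR-133a-3p, miR-133b-3p, miR-206-3p, miR-499-5p, miR-122-5p, miR-451-5p, miR-16-5p, miR-21-5p, miR-146a-5p, miR-155-5p, miR-210-3p, miR-34a-5p and miR-223-3p; miR-486 is not in the table and was not analysed here. Alternatives chosen before the data were examined were DESeq2 size factors (RLE), no low-count filter, DESeq2 for the tests, a replicate block, an erythrocyte covariate, leaving out each library in turn, fitting only the 2 groups compared, and Ta alone for the time comparisons. Added after the data were seen were an analysis without the 6 libraries under 20000 counts, thinning to 100000 counts for the time comparisons, and adjustment over all 31 comparisons at once.

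Lists of 159 miRNA names in 16 lists were written from general knowledge, and 135 of the names are in the table: skeletal and cardiac muscle, erythrocyte and haemolysis, liver, platelet and megakaryocyte, lymphocyte and other leukocyte, inflammation response, fibrosis, hypoxia, p53 targets, brain and neuron, pancreas, kidney, Dlk1-Dio3 cluster, let-7 family, miR-17-92 and paralogous clusters, and epithelium. Some miRNAs stand in more than 1 list, so lists are not independent: miR-21-5p is in inflammation and fibrosis, miR-192-5p and miR-194-5p in liver and p53 targets, miR-146a-5p and miR-155-5p in lymphocyte and inflammation, and the erythrocyte and miR-17-92 lists share 5 members. Lists with 3 or more measured members were tested with fry, which asks whether the members change at all as a set, and with camera, which asks whether they change more than the other miRNAs, at its preset correlation of 0.01 and again with an estimated correlation. List p-values were adjusted within each family of tests.

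The pipeline was tested on simulated data in which known miRNAs were changed in the DU libraries, or in all 3 mo libraries for 3 mo against 1 mo. Each rate below came from 1 simulation with 17 to 20 changed miRNAs tested. Of miRNAs changed 4-fold and 32-fold it called 17.6% and 55.6% at 1 mo, 0% and 0% at 3 mo, 0% and 0% at 6 mo, 5% and 57.9% at 12 mo, 20% and 68.4% in the average over time points, and 47.4% and 80% between 3 mo and 1 mo. In the last of these, 13 of 272 unchanged miRNAs were also called. Of unchanged miRNAs in the DU comparisons, 0 were called at 1, 3 and 6 mo, 2 of 172 at 12 mo and 2 of 273 in the average. Further simulations covered only 3 mo against 1 mo. Without any change 0 to 5 miRNAs were called there and 8.01% to 11% of p-values fell under 0.05. Where 40 miRNAs were changed, 8% to 26.7% of the calls were of unchanged ones. A single call therefore carries less weight than its adjusted p.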

Results

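Serum small RNA was sequenced from male Sprague-Dawley rats carrying metal pellets in the gastrocnemius muscle, to look for circulating miRNAs that mark exposure to an embedded metal. The pellets were of tantalum (Ta, an inert metal used as the surgical control), tungsten (W), nickel (Ni), cobalt (Co), iron (Fe), copper (Cu), aluminium (Al), lead (Pb) or depleted uranium (DU). Serum was taken 1, 3, 6 and 12 mo after implantation. The 138 libraries form 35 groups with n = 4, except Ta and W at 6 mo with n = 3; there was no Ni group at 12 mo.

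Library totals ran from 518 to 6406599 counts (median 685384.5), and a library detected a median of 177 miRNAs (22 to 267). The 3 mo libraries were the poorest, with a median of 286094 counts and 99.5 miRNAs detected, against 1114449 counts and 216 miRNAs at 1 mo, 1302182.5 and 170 at 6 mo, and 558752.5 and 186.5 at 12 mo. There were 6 libraries under 20000 counts, of which 4 were at 3 mo, 1 of them a Ta library; the smallest of the other libraries had 70454.

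**Figure D1:**
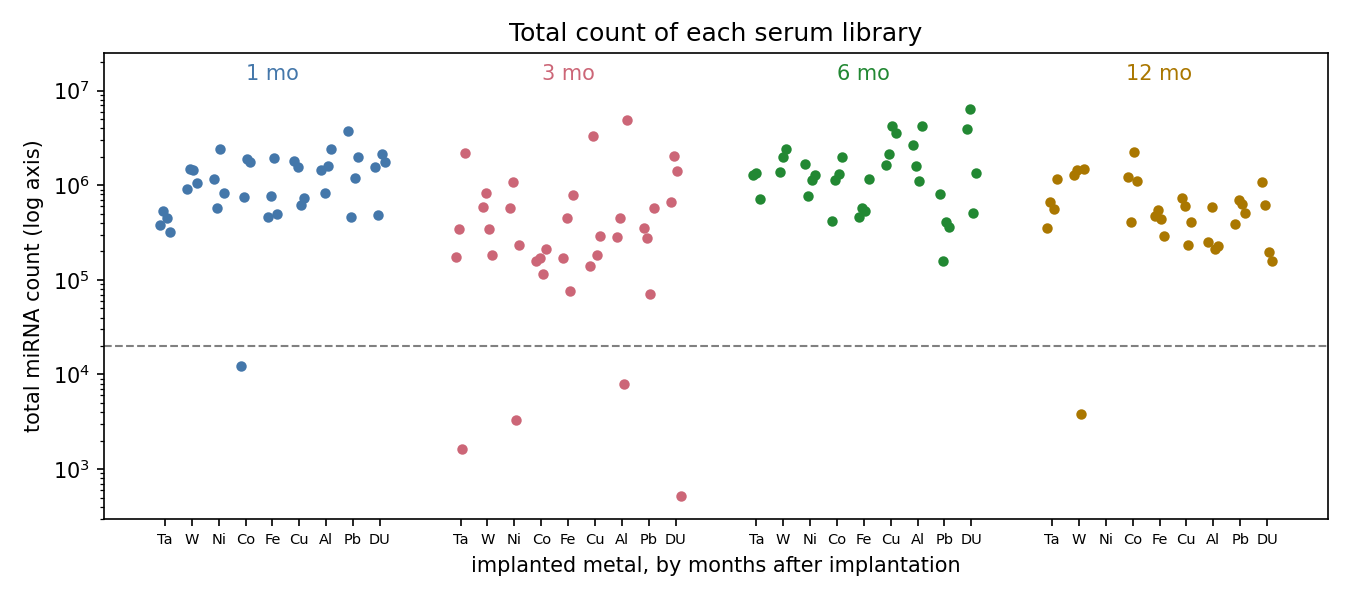
Total counts per library by time point, on a log axis. The dashed line marks 20000 counts.

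A few miRNAs held most of the counts. The miRNA miR-191a-5p, abundant in blood cells and their vesicles, took 22.9% of all counts, followed by the HOX-cluster miRNAs miR-10a-5p (16.2%) and miR-10b-5p (6.93%), the hepatocyte miRNA miR-122-5p (5.34%) and miR-24-3p (4.47%). Among the 132 libraries over 20000 counts, miR-191a-5p ranged from 1.12% to 62.0% of the counts and miR-122-5p from 0.123% to 34.2%. Time point, more than metal, ordered the libraries. On the first principal component (24.85% of the variance, 326 miRNAs) time explained 0.503 of the spread and metal 0.0466, and the component also correlated with the log library total (absolute r = 0.560).

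Few serum miRNAs were called between any metal and Ta at a given time. Power was low: in simulated data 0% of miRNAs changed 4-fold or 32-fold were called at 3 and 6 mo, so few calls do not show few differences. Most calls were in Pb at 6 mo, where a set of miRNAs present in every Ta serum was missing, in libraries that detected fewer miRNAs altogether. At 1 mo miR-30d-5p was lowest in the Ta rats, the calls in Co and W at other times rested on 1 near-empty library each, and 1 call in DU missed the threshold, at an unchanged difference, when single libraries were left out. In 31 comparisons edgeR made 14 calls in 6 comparisons; 1 call remained when the p-values were adjusted over all 31 together, that of miR-322-3p in Pb at 6 mo (adjusted p = 9.75e-05).

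In Pb at 6 mo 8 miRNAs fell and none rose by edgeR. The 4 Pb libraries detected 70 to 96 miRNAs against 168 to 223 in Ta, so a loss of kinds of miRNA in general cannot be separated from an effect of Pb. Each of them had counts in 3 of 3 Ta libraries and none in 4 of 4 Pb libraries. The largest loss was of miR-322-3p, the rodent counterpart of human miR-424 and a product of an X-linked cluster induced in muscle differentiation and hypoxia: 1110 ± 639 CPM in Ta, at least 987-fold lower in Pb (adjusted p = 3.66e-06). Next was miR-126a-5p, from an endothelial gene, with 285 ± 241 CPM in Ta and at least 253-fold lower (adjusted p = 0.00217). The passenger strand miR-191a-3p (427 ± 441 CPM, at least 379-fold lower) and the collagen-targeting miR-29b-3p (479 ± 286 CPM, at least 425-fold lower) shared an adjusted p of 0.00462. The other 4 calls were named after the values were seen. They were miR-6216, of unknown function (229 ± 244 CPM, at least 203-fold, adjusted p = 0.0177), the little-studied miR-676 (147 ± 98.4 CPM, at least 131-fold, adjusted p = 0.0177), the cell cycle miRNA miR-15b-5p (111 ± 64.9 CPM, at least 98.9-fold, adjusted p = 0.0197) and the sensory-cell miRNA miR-96-5p (196 ± 323 CPM, at least 174-fold, adjusted p = 0.04). Several of these means and bounds lean on 1 Ta library. The highest Ta values of miR-191a-3p and miR-126a-5p were 927 and 561 CPM at medians of 263 and 175, though neither call was lost when any 1 library was left out (adjusted p up to 0.0226 and 0.0144). For miR-96-5p the highest Ta value was 569 CPM and the median 12.5, and the call was lost without Ta replicate 1 (adjusted p = 0.31) or any of the 4 Pb libraries (0.0675 to 0.0822). For miR-6216 the highest was 510 CPM and the median 93.4, and the call was lost without Ta replicate 2 (adjusted p = 0.0545). With an erythrocyte covariate only the call of miR-322-3p remained, and with only the Pb and Ta groups fitted miR-322-3p had an adjusted p of 0.0583, the highest over its alternatives (lowest 1.07e-13). DESeq2 called 52 miRNAs in this comparison, of which 7 rose and 45 fell, and with RLE size factors 1 of 8 calls by edgeR was of a riser.

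**Figure D2:**
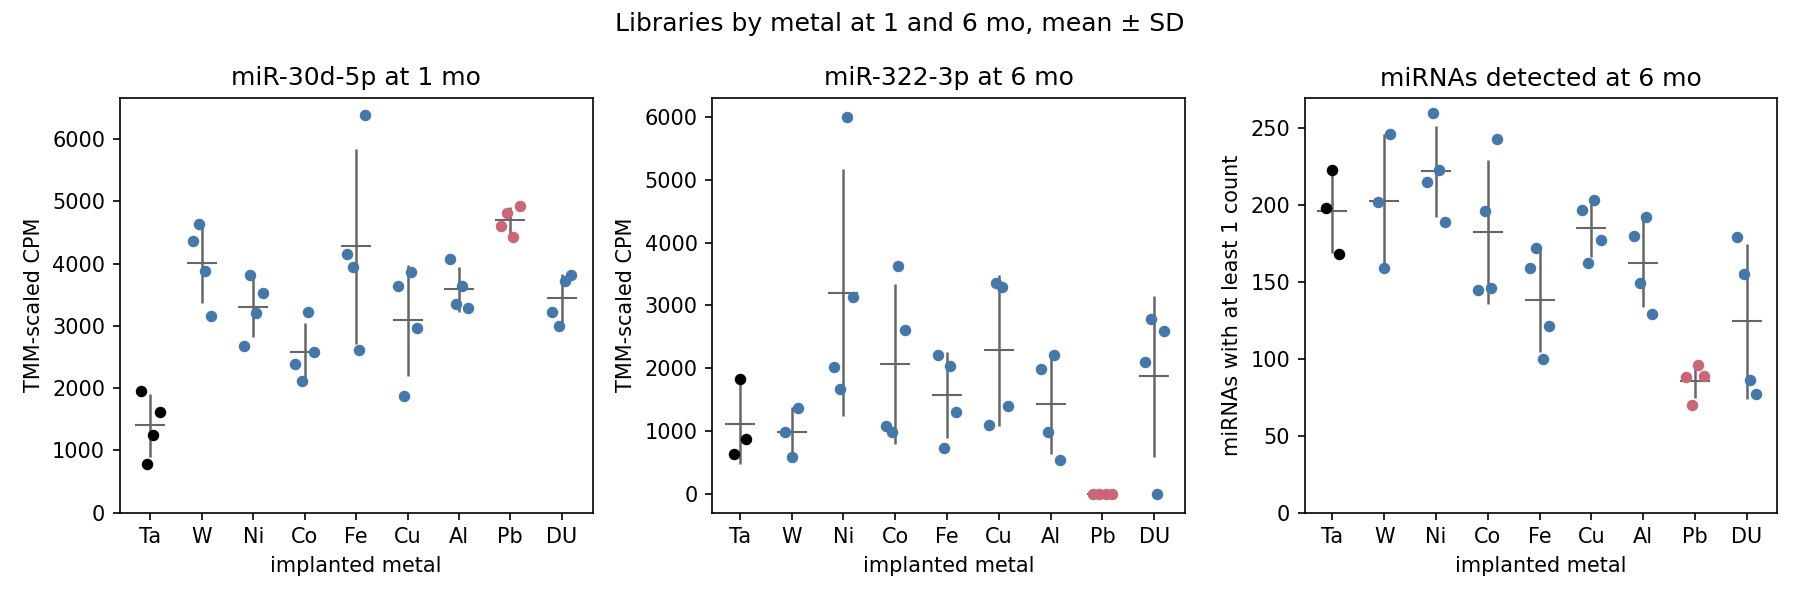
Serum miR-30d-5p at 1 mo, miR-322-3p at 6 mo and number of miRNAs detected at 6 mo, by metal. Points are libraries; dash and bar are mean ± SD. Ta is black and Pb is red.

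At 1 mo miR-30d-5p, an epithelial and islet miRNA that also circulates in plasma, rose in Fe (4275 ± 1561 against 1400 ± 504 CPM in Ta, n = 4 each, log2 1.61 ± 0.37, adjusted p = 0.0305) and in Pb (4692 ± 221 CPM, log2 1.75 ± 0.37, adjusted p = 0.0108). Ta had the lowest mean of 9 groups, and the metal means ran from 2576 CPM in Co (log2 0.88) to 4692 in Pb. The contrast therefore set Ta apart from all metals and was not particular to Fe or Pb. W came next (log2 1.52, adjusted p = 0.0615). With RLE size factors both differences were smaller (log2 1.21 ± 0.40 and 1.44 ± 0.40) and both calls ended (adjusted p = 0.524 and 0.163; 0.00823 to 0.765 in Fe and 0.000855 to 0.408 in Pb over all alternatives). The Fe call was lost when any 1 of 7 of its 8 libraries was left out (adjusted p = 0.0318 without Fe replicate 3, and 0.0792 to 0.404 without any other), though its log2 then stayed at 1.32 to 1.63, and the Pb call without Ta replicate 2 (0.0555) or Ta replicate 3 (0.0723), with log2 1.56 and 1.66. Both metals share the Ta libraries. With labels shuffled at 1 mo, which keeps that sharing, any miRNA was called in 2 or more metals in 1 of 99 draws. At 12 mo miR-30d-5p rose in W (39374 ± 64692 against 4594 ± 726 CPM, log2 3.09 ± 0.70, adjusted p = 0.0176), a call that rested on W replicate 3, a library of 3789 counts, and was lost without it (log2 0.90, adjusted p = 0.333).

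At 3 mo 2 miRNAs fell in Co. The red-cell and platelet miRNA miR-16-5p fell from 47952 ± 92874 CPM in Ta to 189 ± 347 in Co (log2 -7.98 ± 2.10), and the widely expressed growth suppressor miR-26a-5p fell from 81961 ± 127511 to 6006 ± 2825 CPM (log2 -3.77 ± 1.01), each with adjusted p = 0.0377. Both rested on Ta replicate 3, a library of 1645 counts: without it the log2 values were -2.94 (adjusted p = 0.418) and -1.41 (adjusted p = 0.332). Without Co replicate 4 miR-16-5p had an adjusted p of 0.0574. At 12 mo miR-378b, of the muscle and fat metabolism family miR-378, rose in DU: 135 ± 178 CPM in 3 of 4 libraries against 0 of 4 in Ta, at least 137-fold (adjusted p = 0.0377). Mean and bound lean on 1 DU library (389 CPM, median 74.9). That call was lost without Ta replicate 2 (adjusted p = 0.0748), Ta replicate 3 (0.136) or DU replicate 2 (0.0543), although the fitted difference was no smaller in any of these.

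In the other 25 comparisons edgeR called 0 miRNAs. Unadjusted p-values under 0.05 were found there for 22 to 33 miRNAs at 1 mo, 9 to 21 at 3 mo, 4 to 43 at 6 mo and 20 to 39 at 12 mo, and DESeq2 called 3 to 9, 3 to 14, 4 to 19 and 3 to 25. Over all 31 comparisons 760 of 7240 edgeR tests (10.5%) had p under 0.05, and DESeq2 made 333 calls. No miRNA list passed fry at a single time (0 of 418 tests, smallest adjusted p = 0.0558). At its preset correlation camera called 15. The let-7 family, differentiation miRNAs abundant in blood, was higher than in Ta in W at 1 mo (adjusted p = 0.0168), in Co (0.0228) and Fe (0.0028) at 3 mo, and in W (0.000269), Co (0.0228), Fe (0.0228), Cu (0.0028) and DU (0.00409) at 6 mo. At 12 mo it was lower in Cu (adjusted p = 0.00432), Al (0.013) and DU (9.39e-05). The metals at 1 time point are set against the same Ta libraries. A shift in Ta alone could therefore give the let-7 calls of several metals at that time. Muscle miRNAs were higher at 3 mo in Ni (adjusted p = 0.00955) and Pb (0.00108), and kidney miRNAs in Al at 3 mo (0.047) and Co at 6 mo (0.0476). With an estimated correlation none of these remained (smallest adjusted p = 0.988).

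Averaged over time points, edgeR called a handful of miRNAs each in Pb and DU against Ta and almost none in the other metals. In simulated data 20% of miRNAs changed 4-fold were called in such an average, so few calls do not show that few miRNAs differed. The miRNAs that fell in Pb overlapped those of 6 mo. Because the 6 mo libraries are part of the average, this overlap is no separate finding. For miR-322-3p the fitted log2 differences were -0.28, -1.28, -13.3 and 0.95 at 1, 3, 6 and 12 mo. In DU miR-34c-5p, a p53-induced miRNA, and miR-191a-5p, the most abundant miRNA of these sera, rose, and miR-503-5p from the X-linked cluster of miR-322 fell. Of the always-given miRNAs only the red-cell ones were called, miR-451-5p in Cu and DU and miR-16-5p in Pb, and these calls were lost without the near-empty libraries.

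In Pb 14 miRNAs fell, at n = 16 against 15 libraries. Most were detected in fewer Pb than Ta libraries: miR-322-3p in 10 of 16 against 13 of 15 (1845 ± 1958 against 2255 ± 1801 CPM, adjusted p = 0.00873), the cartilage miRNA miR-455-3p in 4 against 7, the liver strand miR-122-3p in 4 against 10, miR-191a-3p in 9 against 13, miR-96-5p in 6 against 12 and miR-32-5p in 1 against 4 (adjusted p = 0.0229 for each of the last 5). Then came miR-6216 in 9 against 11, the little-studied miR-872-3p in 4 against 8 and the passenger strand miR-340-3p in 4 against 6 (adjusted p = 0.0448 each), and the endothelial miR-126a-5p in 11 against 13 (adjusted p = 0.0456). The always-given miR-16-5p also fell (871 ± 615 against 20323 ± 74434 CPM, log2 -1.96 ± 0.62, adjusted p = 0.0467). Named after the values were seen were miR-15b-5p and miR-29b-3p (adjusted p = 0.0467 each) and miR-450a-3p (adjusted p = 0.0477). The count of 14 was not stable. It was 6 with RLE size factors, 5 with a replicate block and 1, of miR-322-3p, without the near-empty libraries, and leaving out 1 library moved it over 1.5 times in 26 of 31 cases, down to 1. As a set, erythrocyte miRNAs fell in Pb (fry, adjusted p = 0.0254), with 1 of 10 members called and 3 when adjusted over the list alone. The miR-17-92 clusters, growth-promoting miRNAs of dividing blood cells, fell too (adjusted p = 0.0254, 0 of 11 members called), as did fibrosis miRNAs (adjusted p = 0.0475, 1 of 7). None of these 3 sets passed camera (adjusted p = 0.179, 0.229 and 0.441), and the 1 erythrocyte member called was miR-16-5p.

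In DU 5 miRNAs rose and 7 fell, a count of 12 that was 3 with a replicate block and that moved over 1.5 times in 5 of 31 cases when 1 library was left out, down to 1 without Ta replicate 3 at 6 mo. Risers were miR-34c-5p (in 8 of 16 DU libraries against 1 of 15 in Ta, adjusted p = 0.0177), miR-3074 from the miR-24 locus (7 against 0, adjusted p = 0.0213), miR-191a-5p (349842 ± 339255 against 162495 ± 190937 CPM, log2 1.55 ± 0.43, adjusted p = 0.0307), the leukocyte miRNA miR-142-3p (5 against 0, adjusted p = 0.0343) and miR-542-3p (7 against 2, adjusted p = 0.0344). Fallers were miR-503-5p, a cell cycle brake (6 of 16 against 11 of 15, adjusted p = 0.00108), miR-455-3p (5 against 7, adjusted p = 0.0177), miR-32-5p (1 against 4, adjusted p = 0.0307), miR-130b-5p (2 against 8, adjusted p = 0.0338), miR-450a-5p (7 against 11), the red-cell miRNA miR-451-5p (log2 -1.69 ± 0.52; -0.60 without the near-empty libraries, adjusted p = 1, and 0.00349 to 1 over the alternatives) and the epithelial miR-200b-5p (6 against 7), the last 3 at adjusted p = 0.0394. In Fe 1 miRNA fell, again miR-503-5p (7 of 16 libraries, 115 ± 222 against 304 ± 356 CPM, adjusted p = 0.004). In Cu 1 fell, miR-451-5p (log2 -2.32 ± 0.53, adjusted p = 0.00743); without the near-empty libraries its adjusted p was 0.407 (3.98e-05 to 0.407 over the alternatives).

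In W, Ni, Co and Al edgeR called 0 miRNAs, with 31, 28, 48 and 20 at an unadjusted p under 0.05 and 47, 35, 73 and 31 called by DESeq2. The liver marker miR-122-5p moved between log2 -0.02 in Pb and 0.68 in Al. Injury- and inflammation-related miR-21-5p lay between -0.11 in Al and 0.69 in W, and the brake on inflammation miR-146a-5p between -1.48 in Co and -0.22 in Cu (smallest adjusted p = 0.119). The neutrophil miRNA miR-223-3p ranged from -0.46 to 0.76. The leukocyte miRNA miR-155-5p was detected in 5 of 16 DU libraries against 7 of 15 in Ta (adjusted p = 0.448, the smallest of the 8 metals). Of the muscle miRNAs, miR-1-3p ranged from -0.23 in Al to 3.18 in Ni (adjusted p = 0.347), and miR-206-3p from -0.69 to 1.29, while miR-133a-3p was detected in 7 of 12 Ni libraries against 3 of 11 in Ta (adjusted p = 0.0883, the smallest of the 8 metals). The red-cell miRNA miR-16-5p was below Ta in all 8 metals (log2 -2.14 in Co to -1.62 in DU) with unadjusted p under 0.05 in 8 of 8, but all share the near-empty Ta library of 3 mo, and without the near-empty libraries the values were -0.34 in Co to 0.20 in Ni. For miR-451-5p the values lay between -2.32 and -1.04. By camera the let-7 family was higher than in Ta in W (adjusted p = 5.6e-07, or 0.563 with an estimated correlation), Co (0.0149, or 0.994) and Fe (4.67e-05, or 0.677). Muscle miRNAs were higher in Ni (0.0103, or 0.851, with 3 of 8 members when adjusted over the list alone). The let-7 results in W, Co and Fe share their Ta libraries.

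Differences from Ta also shifted between time points. The miRNAs called in the largest number of metals, miR-26a-5p and miR-16-5p, were high at 3 mo in 1 near-empty Ta library, so their calls do not show an effect of the metals. In every metal miR-26a-5p was called, below Ta at 3 mo (log2 -2.61 in Fe to -4.71 in Co) and between -0.55 and 1.65 at the other times; fitted to the 3 mo libraries alone, its mean difference over the metals was -2.81, and -0.35 without the near-empty libraries. The calls numbered 4 in W, 2 in Ni, 7 in Co, 2 in Fe, 4 in Cu, 3 in Al, 13 in Pb and 7 in DU. In W, Co, Cu and Al miR-16-5p followed the same course (log2 -7.00, -9.27, -7.20 and -6.99 at 3 mo), while the platelet and fibroblast miRNA miR-199a-3p lay below Ta at 3 mo in W and Ni (-4.67 and -4.91) and above it at 6 mo (1.72 and 2.22). Without the near-empty libraries, among them a Ta library at 3 mo, the calls in W, Ni and Al were lost. Also apart at 3 mo alone were miR-30a-5p in Al, an epithelial and kidney miRNA (log2 5.44, adjusted p = 0.0066), miR-501-3p (adjusted p = 0.00138), miR-30e-3p (0.00843), miR-148b-3p (0.026), miR-103-3p (0.0352) and miR-25-5p (0.0497) in Co, and miR-145-3p in DU (0.0469).

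Other changes with time were not limited to 3 mo. The circulating miRNA miR-423-5p, studied as a marker in heart failure, lay below Ta at 6 mo and above it at 12 mo in Cu (log2 -1.98 and 2.61, adjusted p = 0.0134), Pb (-1.65 and 1.38, adjusted p = 0.0189) and DU (-2.15 and 2.31, adjusted p = 0.00854). The same 3 metals shared miR-378b, fitted below Ta at 1 mo and above it at 12 mo, where no Ta library had it (adjusted p = 0.0156 in Cu, 0.0189 in Pb and 0.0122 in DU). All 3 metals were set against the same Ta libraries, so for both miRNAs 1 shift in Ta could give all 3 calls. In Fe and DU miR-503-5p was missing at 3 and 6 mo only (adjusted p = 0.024 and 0.00854). Pb added the 6 mo losses of miR-322-3p (adjusted p = 0.00162), miR-6216 (0.0111), miR-126a-5p, miR-191a-3p and miR-29b-3p (0.0189 each) and miR-676 (0.0305). Further Pb calls were miR-330-3p (adjusted p = 0.0117), miR-6328 (0.0302), miR-30d-3p (0.0304) and the muscle miRNA miR-133a-3p (0.0364). In W miR-30d-5p was called as well (adjusted p = 0.0453), and in DU miR-664-3p (0.0469). The W call had its largest difference at 12 mo (log2 3.76), where 1 near-empty W library carried it. It was lost without the near-empty libraries.

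More miRNAs were called between time points, with 30 or 32 libraries a side, than between any metal and Ta, with at most 16. At 3 mo let-7 miRNAs, the neutrophil miRNA miR-223-3p and 3 of 8 muscle miRNAs rose while miR-191a-5p and a long tail of low-abundance miRNAs fell. At 6 and 12 mo fewer miRNAs differed from 1 mo. What grew instead was the liver signal: miR-122-5p, made almost only by hepatocytes, lay above 1 mo at each later time and had the smallest p at 12 mo. Rats also grew older over these months, and neither age nor the handling of the samples can be separated from time since implantation here.

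**Figure D3:**
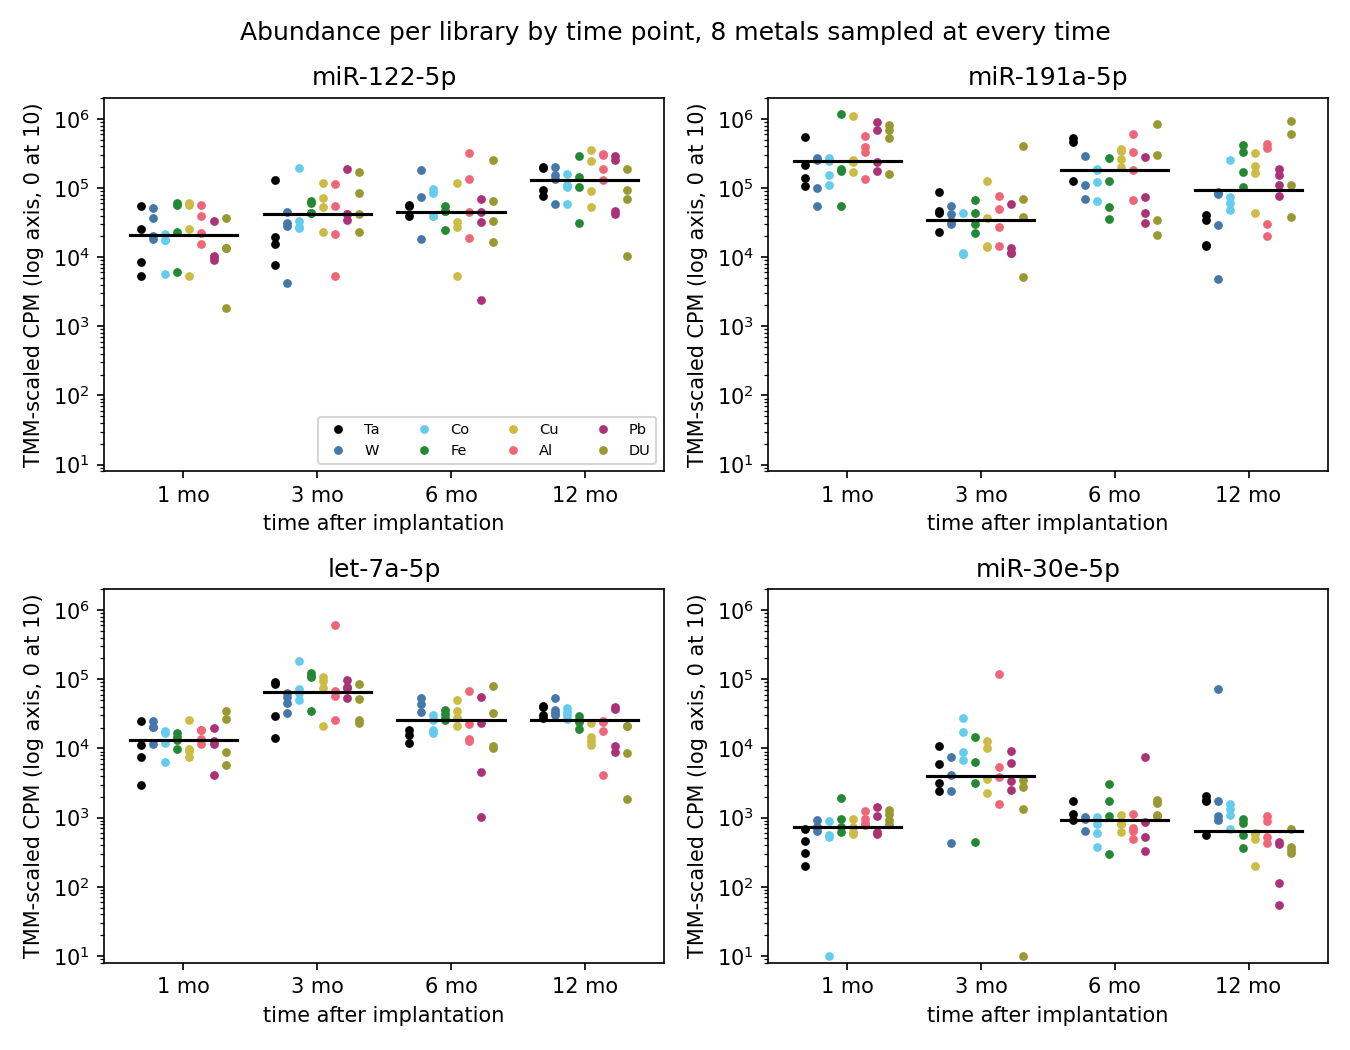
CPM of miR-122-5p, miR-191a-5p, let-7a-5p and miR-30e-5p by time point, on a log axis with 0 drawn at 10. Points are libraries coloured by metal and bars are medians over libraries.

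At 3 mo against 1 mo 26 miRNAs rose and 114 fell (32 libraries each). The median log2 change of all tested miRNAs was -1.63, or -1.28 with RLE size factors, so a change is best read against that shift; in Ta rats alone, with 4 libraries a side, 6 miRNAs were called, 1 of them miR-16-5p, which a near-empty library carried. The fall with the smallest p was of miR-191a-5p, from 357072 ± 300680 to 49089 ± 69960 CPM (log2 -2.97 ± 0.31, adjusted p = 2.45e-14). Still detected in most libraries were also the cartilage miRNA miR-140-3p (5948 ± 2584 to 1511 ± 1520 CPM, log2 -2.10 ± 0.31, adjusted p = 2.93e-08) and miR-24-3p (56896 ± 20495 to 22253 ± 14814 CPM, log2 -1.38 ± 0.21, adjusted p = 6.56e-08). Others dropped out of many libraries: miR-351-3p of the X-linked cluster (31 of 32 libraries at 1 mo, 12 at 3 mo, adjusted p = 2.16e-10), the sensory and epithelial miR-183-5p (31 to 6, adjusted p = 3.91e-08), the mirtron miR-877 (31 to 9, adjusted p = 6.56e-08), miR-455-3p (27 to 2, adjusted p = 7.56e-08), the passenger strand miR-125b-2-3p (31 to 9, adjusted p = 1.15e-07), the smooth muscle miR-145-5p (30 to 12) and miR-25-5p (31 to 16), both at adjusted p = 2.63e-07.

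The rise at 3 mo was led, by p, by let-7a-5p, from 14669 ± 7368 to 84461 ± 101640 CPM (log2 2.40 ± 0.25, adjusted p = 2.45e-14), and miR-30e-5p, a widely expressed miRNA of the miR-30 family, from 792 ± 359 to 9677 ± 20835 CPM (log2 3.18 ± 0.34, adjusted p = 2.58e-14). Of 9 let-7 members 8 rose, among them let-7f-5p (log2 1.67 ± 0.25), let-7g-5p (1.77 ± 0.28), let-7c-5p (1.82 ± 0.30) and let-7b-5p (1.63 ± 0.29); only let-7e-5p did not (0.32, adjusted p = 0.739). As a set the family rose (fry, adjusted p = 2.63e-09; camera, 1.25e-05, or 0.174 with an estimated correlation). Near-identical let-7 sequences may be hard to tell apart in short reads. The shared passenger strand of let-7a-1 and let-7c-2 rose with them, from 11 to 13 of 32 libraries and from 11.6 to 233 CPM (adjusted p = 1.21e-05). Further risers were miR-223-3p (458 ± 434 to 3195 ± 3556 CPM, log2 2.75 ± 0.41, adjusted p = 2.51e-08), miR-451-5p (log2 1.97 ± 0.36, adjusted p = 3.47e-06) and miR-199a-3p (1.82 ± 0.37, adjusted p = 2.04e-05). The value of miR-451-5p takes in the near-empty Ta library of 3 mo, where it held 22.74% of the counts against at most 1.862% in the other Ta libraries. The liver miRNAs miR-122-5p (1.16 ± 0.30, adjusted p = 0.000639; 0.0669 with an erythrocyte covariate, 2.58e-11 to 0.607 over the alternatives) and miR-194-5p (2.67 ± 0.65, adjusted p = 0.000305) rose, and so did miR-30d-5p (1.43 ± 0.26, adjusted p = 2.14e-06) and miR-21-5p (1.13 ± 0.27, adjusted p = 0.00023). No call was made for the other red-cell miRNA, miR-16-5p (-0.11, adjusted p = 1), an average that takes in a log2 of 6.28 in Ta alone, carried by 1 near-empty library.

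Muscle miRNAs, which leak from injured fibres, rose at 3 mo: miR-1-3p (698 ± 2295 to 2497 ± 4521 CPM, log2 2.76 ± 0.73, adjusted p = 0.00081), the satellite cell miRNA miR-206-3p (1.86 ± 0.53, adjusted p = 0.002) and miR-1b (2.17 ± 0.68, adjusted p = 0.00516). These 3 of 8 members carried the set upward (fry, adjusted p = 0.0425; camera 0.219), while the median over the members was -0.32. In Ta rats alone miR-1-3p and miR-1b had negative values within their error (log2 -0.27 ± 2.05 and -0.95 ± 1.99), which show neither a rise nor a fall. The 1 mo mean of miR-1-3p leaned on Cu (3194 ± 6116 CPM). At 1 mo Co and Fe lay at 1083 and 966 CPM, and Al, DU, Pb, Ta and W at 28.2 to 95.9. The rest of the myomiRs were rare. At 3 mo miR-133a-3p was seen in 8 of 32 libraries and miR-133b-3p in 3, and miR-499-5p in none.

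**Figure D4:**
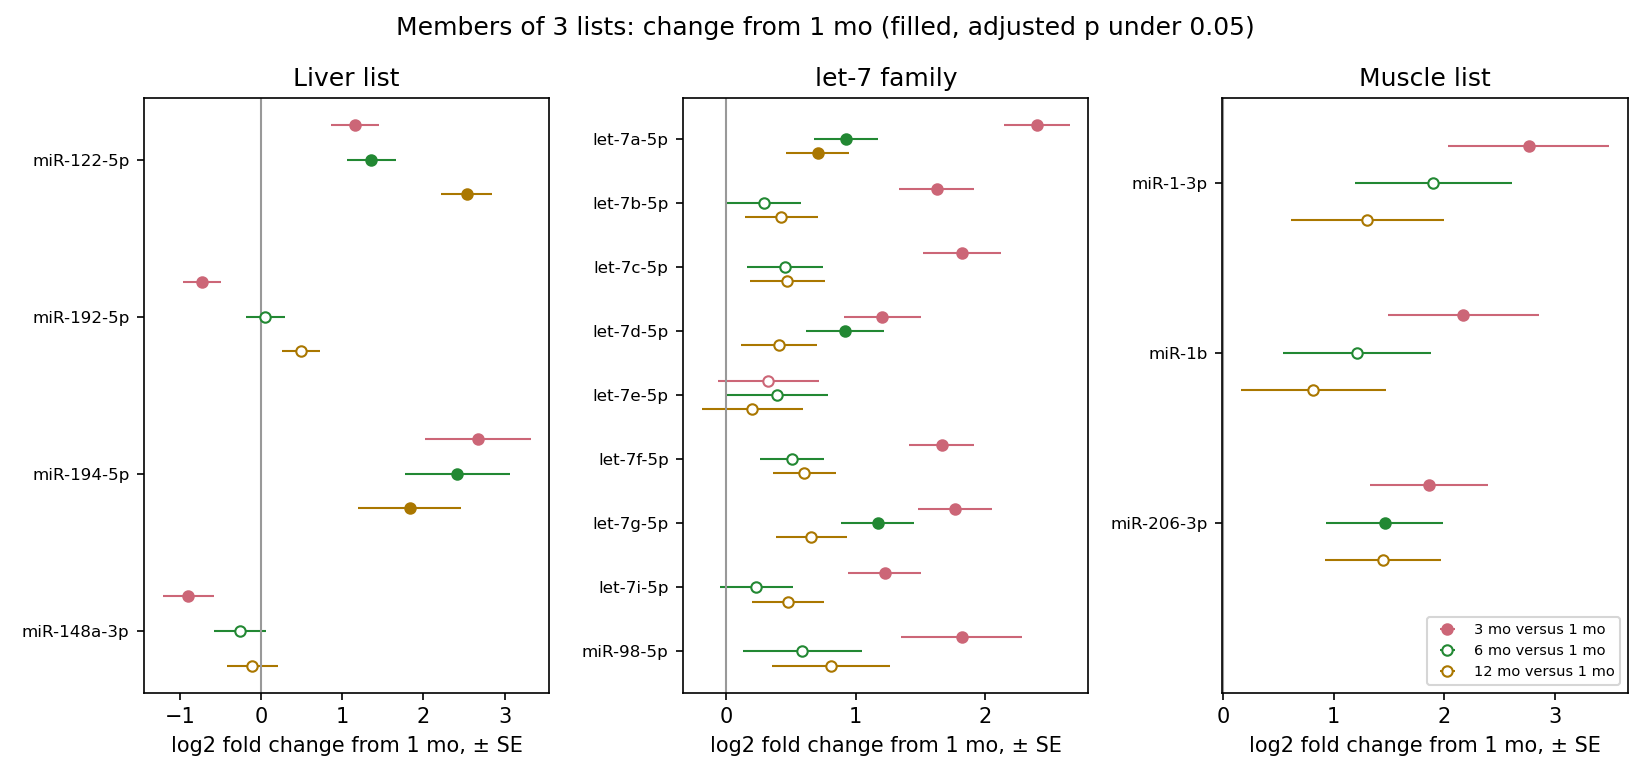
Change from 1 mo, as log2 ± SE, of liver (miR-122-5p, miR-192-5p, miR-194-5p, miR-148a-3p), let-7 family and muscle (miR-1-3p, miR-1b, miR-206-3p) miRNAs. Filled symbols are called. List members with a large or missing standard error at any time are not drawn. The muscle panel therefore shows only part of its list, without the rarer members.

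Sets that passed fry downward at 3 mo did so while most miRNAs fell. None of them fell more than the other miRNAs by camera (smallest adjusted p = 0.291, platelet). Platelet miRNAs fell as a set (fry, adjusted p = 1.44e-10; 2 rose, 4 fell and 5 when adjusted over the list alone), with miR-24-3p and miR-191a-5p down and miR-223-3p up. Fibrosis miRNAs fell (adjusted p = 0.000139; 2 rose and 4 fell), among them the collagen-repressing miR-29b-3p (31 of 32 libraries to 10) and the fibroblast miRNA miR-214-3p (31 to 12). Lymphocyte miRNAs fell (adjusted p = 0.0011; 3 of 8), with the T-cell-rich miR-342-3p down (-1.97 ± 0.39, adjusted p = 1.1e-05) and miR-146a-5p down by TMM scaling only (-1.11 ± 0.35, adjusted p = 0.00566; -0.22 with RLE size factors, adjusted p = 0.916; 1.13e-05 to 0.916 over the alternatives). Epithelial miRNAs fell (adjusted p = 0.00221; 3 of 10), as did the erythrocyte (0.00562; 1 rose, 3 fell), kidney (0.00772; 1 rose, 3 fell) and p53-target lists (0.0425; 1 rose, 3 fell). The remaining sets did not pass: inflammation (adjusted p = 0.271; 1 rose, 2 fell), brain (0.592; 1 of 7 fell), liver (0.682; 2 rose and 2 fell, miR-192-5p and miR-148a-3p, both lost with RLE size factors), Dlk1-Dio3 (0.719; 3 of 11 fell) and miR-17-92 (0.997; 2 of 11 fell). The pancreas list had 2 measured members, of which the islet miRNA miR-375-3p rose (log2 1.33 ± 0.38, adjusted p = 0.00212) and the acinar miR-217-5p fell (10 of 32 libraries to 2, adjusted p = 0.00225), and the hypoxia list had 1, miR-210-3p, seen in 6 libraries at 1 mo and in none at 3 mo.

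At 6 mo against 1 mo 6 miRNAs rose and 40 fell (30 against 32 libraries, median log2 -0.76, or -0.68 with RLE size factors). First by p was miR-322-3p (5151 ± 2119 to 1482 ± 1082 CPM, 32 of 32 libraries to 25 of 30, adjusted p = 4.76e-06), absent from all 4 Pb libraries, followed by miR-140-3p (log2 -1.54 ± 0.32) and miR-29b-3p (31 of 32 libraries to 21 of 30), each at adjusted p = 0.000405. Detections of miR-503-5p went from 31 to 15 and of miR-455-3p from 27 to 12 (adjusted p = 0.000599 each), and of the pigment-cell miRNA miR-211-3p from 19 to 5 (0.000606). Further losses were of miR-24-2-5p (30 to 12, adjusted p = 0.00117), miR-455-5p (12 to 2, 0.00164), miR-181a-1-3p (20 to 8, 0.00164) and miR-219a-1-3p (14 to 3, 0.00169). Risers were miR-122-5p (26410 ± 19182 to 69279 ± 71128 CPM, log2 1.36 ± 0.30, adjusted p = 0.00079), let-7g-5p (1.17 ± 0.28, 0.00169), let-7a-5p (0.93 ± 0.25, 0.00453), let-7d-5p (0.91 ± 0.30, 0.0259), the hepatic and p53-induced miR-194-5p (2.42 ± 0.65, 0.00491) and miR-206-3p (1.46 ± 0.53, 0.046; 0.0862 with a replicate block and 0.0553 without the near-empty libraries). The macrophage and lymphocyte miRNA miR-155-5p fell (24 of 32 libraries to 7 of 30, adjusted p = 0.00453), a call lost with an erythrocyte covariate (0.06; 4.46e-14 to 1 over the alternatives). No call was made at 6 mo for miR-1-3p (1.90, adjusted p = 0.0567), miR-451-5p (0.90, 0.0882), miR-223-3p (0.90, 0.117), miR-146a-5p (-0.82, 0.12), miR-133a-3p (11 of 32 libraries to 17 of 30, 0.141), miR-21-5p (0.36, 0.535) or miR-16-5p (-0.33, 0.981).

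Sets at 6 mo moved in 2 directions. Liver miRNAs stood above the other miRNAs (camera, adjusted p = 0.00033, or 0.0243 with an estimated correlation; fry 0.234; 2 of 7 rose), and so did the let-7 family (camera 7.79e-10, or 0.0243; fry 0.0225; 3 of 9 rose). For muscle miRNAs camera gave 0.0118, or 0.498 with an estimated correlation (fry 0.987; 1 of 8 rose, 2 when adjusted over the list alone). Other sets passed fry downward, though none fell more than the other miRNAs by camera (smallest adjusted p = 0.58). They were lymphocyte (adjusted p = 9.87e-07; 1 of 8), miR-17-92 (3.32e-05; 2 of 11), brain (0.000261; 0 of 7), fibrosis (0.000262; 1 of 7), platelet (0.00129; 1 of 8), erythrocyte (0.00166; 2 of 10, with 1 riser when adjusted over the list alone), inflammation (0.00176; 1 of 8), Dlk1-Dio3 (0.00788; 1 of 11), epithelium (0.0123; 0 of 10) and kidney (0.0389; 0 of 7). The p53 targets did not pass (0.0992; 1 rose).

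At 12 mo against 1 mo 15 miRNAs rose and 22 fell (32 libraries each, median log2 -0.26, or -0.38 with RLE size factors). Serum miR-122-5p rose from 26410 ± 19182 to 148567 ± 92329 CPM (log2 2.53 ± 0.31, adjusted p = 1.01e-10), higher in 8 of 8 metals including Ta, by log2 1.95 to 3.32. Its passenger strand miR-122-3p came with it (18 of 32 libraries to 24, adjusted p = 0.003), as did the liver and islet miRNA miR-802-5p (7 to 17, adjusted p = 0.000897), miR-193a-5p (8 to 18), the keratinocyte miR-203b-3p (12 to 18) and miR-1247-5p (12 to 25; adjusted p = 0.00121 for these 3). Also up were miR-101b-3p (log2 2.18 ± 0.52, adjusted p = 0.00123), let-7a-1-3p and let-7c-2-3p, which share 1 sequence (11 to 19 libraries, 0.00938), and miR-21-5p (0.87 ± 0.27, 0.0186; 0.0679 without the near-empty libraries and 0.000146 to 0.461 over the alternatives). Liver miRNAs rose as a set (fry, adjusted p = 4.35e-07; camera 0.000206, or 0.0243 with an estimated correlation; 4 of 7), among them miR-194-5p (1.83 ± 0.63, 0.041; 0.0677 without the near-empty libraries and 0.00645 to 0.392 over the alternatives), while miR-192-5p did not pass (0.49, 0.169).

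Down at 12 mo were miR-423-5p (12504 ± 10045 to 5688 ± 5248 CPM, log2 -1.39 ± 0.24, adjusted p = 5.1e-06), miR-140-3p (-1.61 ± 0.31, adjusted p = 6.81e-05), miR-191a-5p (-1.34 ± 0.30, 0.000785), miR-351-3p (-2.63 ± 0.58, 0.000785) and the lymphocyte strand miR-150-3p (-2.21 ± 0.54, 0.00155). Detections fell for miR-219a-1-3p (14 of 32 libraries to 2, adjusted p = 0.000785), miR-181a-1-3p (20 to 5, 0.00121), the imprinted-cluster miRNA miR-409a-3p (11 to 0, 0.00123), miR-455-5p (12 to 2, 0.00221) and miR-542-3p (23 to 8, 0.00225). Lymphocyte (fry, adjusted p = 0.00384; 1 of 8) and platelet sets fell (0.0212; 2 of 8) but not more than the other miRNAs (camera 0.1 and 0.369), and the let-7 set was higher than at 1 mo (0.0119; camera 0.0186, or 0.669 with an estimated correlation). Of its 9 members only let-7a-5p was called, and not without the near-empty libraries (adjusted p = 0.0679). Muscle (0.0618; 0 of 8), brain (0.308; 0 of 7), epithelium (0.548; 1 rose), erythrocyte (0.592; 0 of 10), miR-17-92 (0.592; 0 of 11), Dlk1-Dio3 (0.592; 2 of 11 fell), p53 targets (0.682; 1 rose, 1 fell), kidney (0.727; 0 of 7), inflammation (0.997; 1 rose, 1 fell and 2 when adjusted over the list alone) and fibrosis (0.997; 1 rose) did not pass. No call was made for miR-206-3p (1.45, adjusted p = 0.0517), miR-146a-5p (-0.86, 0.0941), miR-1-3p (1.30, 0.247), miR-155-5p (0.93, 0.656), miR-223-3p (0.37, 0.751), miR-451-5p (-0.26, 0.931) or miR-16-5p (0.05, 1). Rarely seen throughout were miR-133b-3p, miR-210-3p, miR-34a-5p and miR-499-5p, in 6, 7, 5 and 6 of 32 libraries at 12 mo.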

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

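Of the tests below, those of depth by thinning, of near-empty libraries, of progression, of batch, of rare miRNAs at 3 mo, of the Ta library behind miR-451-5p and of low diversity in Pb were chosen after the result was seen.

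In groups of 4 a sample was singled out by Dixon's test at the 95% level, which chance passes in about 1 of 20 groups. Among totals, 33 groups were looked at, 3 stood out and chance would give 1.65: DU at 3 mo replicate 4 with 518 counts (others 661218 to 2062074), W at 12 mo replicate 3 with 3789 (others 1269637 to 1490019) and Al at 12 mo replicate 2 with 589967 (others 214246 to 252421). Among CPM of called miRNAs, 19 groups were looked at and 4 values stood out. In Ta at 3 mo replicate 3 miR-26a-5p was at 273100 CPM (others 12950 to 22110) and miR-16-5p at 187300 (others 601.1 to 3196), in Co at 3 mo replicate 3 miR-16-5p was at 709 (others 0 to 26.3), and in W at 12 mo replicate 3 miR-30d-5p was at 136400 (others 6284 to 7828). Differences from Ta that changed with time, tested as an interaction in edgeR, were called for 4 miRNAs in W, 2 in Ni, 7 in Co, 2 in Fe, 4 in Cu, 3 in Al, 13 in Pb and 7 in DU.

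The 3 mo libraries stood apart. Depth, near-empty libraries and a few abundant miRNAs were argued against as the whole cause: after thinning to 100000 counts 87.6% of the calls still tested (106 of 121) kept direction and call, without the near-empty libraries 99.3% did, and without miR-191a-5p, miR-10a-5p and miR-10b-5p 100% did. A change that progresses with age or implantation was argued against as the whole cause too, since 92 miRNAs differed between 12 and 3 mo and 37 between 12 and 1 mo. Libraries set apart at 3 mo for any reason raise the first count, so a progressing part is not excluded. Of the 140 calls at 3 mo, 53 (37.9%) were called in the opposite direction between 3 and 6 mo. Of miRNAs of 1000 CPM or more at 1 mo 76.3% were called (45 of 59, of which 13 rose and 32 fell). Those called were detected in a median of 30 of 32 libraries at 3 mo, so loss of rare miRNAs alone does not account for them. Whether low diversity of these libraries also shifted the shares of abundant miRNAs was not tested. Low diversity stays open for the rarer ones, of which 86.3% of those called fell. Handling as 1 batch cannot be told apart from time, because the labels name a batch for 0 of the libraries.

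In Pb at 6 mo 8 miRNAs had no counts. Depth was argued against: with the 6 mo libraries thinned to 150000 counts 8 of 8 stayed called. The Pb libraries were poor in kinds of miRNA, detecting 70 to 96 (median 88.5) against 168 to 223 in Ta, and by an exact permutation test after thinning p was 0.0286, the smallest that 35 splits can give. Of 49 other miRNAs in the same range of Ta abundance, 14 (28.6%) were seen in at most 1 Pb library. Other poor libraries kept some of the 8: each DU library, with 77 miRNAs or more, had at least 2 of them, and each Fe library, with 100 or more, at least 4. Of the DU libraries as poor as those of Pb, replicate 4 (77 miRNAs) had miR-322-3p at 2597 CPM and replicate 3 (86 miRNAs) had none. The 8 were picked because no Pb library had them, and the 49 leave them out. Pb could therefore not score above the other poor libraries, and neither count can weigh low diversity. Low diversity is not excluded, and it cannot be told apart from an effect of Pb. A loss of these miRNAs under Pb exposure remains a hypothesis.

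At 3 mo miR-451-5p, miR-16-5p and miR-26a-5p were lower in the metals together than in Ta. A candidate explanation is 1 Ta library of 1645 counts, replicate 3, in which miR-451-5p took 22.74%, miR-16-5p 14.71% and miR-26a-5p 21.46% of the counts, against at most 1.862% for miR-451-5p in the other Ta libraries. Without the near-empty libraries the mean difference for miR-451-5p went from log2 -4.01 ± 0.63 to -1.11 ± 0.77, for miR-16-5p from -5.83 to -0.42 and for miR-26a-5p from -2.81 to -0.35. A smaller difference for miR-451-5p in the other libraries stays open (edgeR, unadjusted p = 0.158).

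Each count of called miRNAs was set against other splits of the same samples, the real split included, each comparison taken alone; over the 31 comparisons with Ta together, 14 or more calls came up in 7 of 99 shuffles. So taken, under 0.05 of the splits called as many for Fe at 1 mo (1 call, in 2 of 100 splits, highest other 1), Pb at 1 mo (1 call, 2 of 100, highest other 1), Co at 3 mo (2 calls, 1 of 100, highest other 1), Pb at 6 mo (8 calls, 1 of 100, highest other 1), Pb averaged (14 calls, 1 of 40, highest other 10), DU averaged (12 calls, 1 of 40, highest other 7), the change with time in Pb (13 calls, 1 of 40, highest other 9) and DU (7 calls, 1 of 40, highest other 5), and 3, 6 and 12 mo against 1 mo (140, 46 and 37 calls, 1 of 40 each, highest other 12, 5 and 10). Over 50 counts some would pass in this way by chance, so a pass taken alone does not exclude chance for a comparison with Ta. Without the near-empty libraries Co at 3 mo had 0 calls and Pb averaged had 1. Fe and Pb at 1 mo share their Ta libraries. At least 0.05 of the splits called as many for W at 12 mo (1 call, 11 of 100, highest other 5), DU at 12 mo (1 call, 22 of 100, highest other 8), Fe averaged (1 call, 19 of 40, highest other 11), Cu averaged (1 call, 14 of 40, highest other 16) and the change with time in W (4 calls, 3 of 40, highest other 10), Ni (2 calls, 14 of 40, highest other 18), Co (7 calls, 2 of 40, highest other 7), Fe (2 calls, 6 of 40, highest other 5), Cu (4 calls, 3 of 40, highest other 7) and Al (3 calls, 4 of 40, highest other 9). The comparisons with 0 calls were matched by 100 of 100 splits. Their highest other counts in the order W, Ni, Co, Cu, Al and DU were 1, 2, 1, 3, 1 and 1 at 1 mo; in the order W, Ni, Fe, Cu, Al, Pb and DU 2, 1, 2, 2, 1, 2 and 2 at 3 mo; in the order W, Ni, Co, Fe, Cu, Al and DU 15, 1, 2, 1, 2, 1 and 8 at 6 mo; and in the order Co, Fe, Cu, Al and Pb 6, 4, 5, 8 and 5 at 12 mo. The averages with 0 calls in W, Ni, Co and Al were matched by 40 of 40 splits, with highest others of 12, 9, 10 and 14. Splits calling several times the real count, such as 15 against 0 in W at 6 mo and 18 against 2 for the change with time in Ni, point to a structure of the samples, and its source was not tested.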

How the results depend on the processing

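The tests without libraries under 20000 counts, with thinning and with adjustment over all 31 comparisons were chosen after the results were seen; the others were not. Spread between samples and sparse counts limit these data: dispersion was high (biological coefficient of variation 1.223, 1.991, 1.806 and 1.282 at 1, 3, 6 and 12 mo), RLE size factors rested on 43, 15, 37 and 37 miRNAs without a zero, and 6 libraries were near-empty. The 3 time comparisons kept their counts within 1.5 times under RLE (122, 44 and 44), without the near-empty libraries (141 at 3 mo, 139 of them shared) and under thinning. Of 50 counts 33 stayed within 1.5 times under RLE, 14 without the low-count filter, 44 with the replicate block, 34 with the erythrocyte covariate, 33 without the near-empty libraries and 3 under DESeq2, and of 31 counts 23 stayed with only 2 groups fitted. Except where said, the cause was not tested.

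With RLE size factors Fe and Pb at 1 mo went to 0; at 3 mo W, Ni, Fe, Cu, Al, Pb and DU had 5, 4, 3, 3, 3, 1 and 4; at 12 mo W, Cu, Pb and DU had 5, 2, 3 and 4; averaged W and Pb had 1 and 6; the change with time in W and Co had 11 and 4. Without the low-count filter W, Ni, Co and Fe, then Cu, Al, Pb and DU, had 3, 6, 4, 6, 7, 4, 6 and 6 at 1 mo; W, Ni, Fe, Cu, Al, Pb and DU had 4, 3, 3, 2, 1, 1 and 3 at 3 mo; Ni, Fe, Al and DU had 3, 1, 1 and 2 at 6 mo; W, Co, Fe, Cu, Al, Pb and DU had 9, 4, 1, 4, 5, 8 and 7 at 12 mo. In the averages Ni, Co, Cu, Al and Pb then had 7, 4, 2, 5 and 9, and in the change with time W, Co, Fe, Al and DU had 17, 13, 5, 8 and 11.

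With DESeq2 W, Ni, Co and Fe, then Cu, Al, Pb and DU, had 7, 3, 9, 6, 4, 8, 10 and 8 at 1 mo, 6, 7, 23, 14, 3, 3, 5 and 5 at 3 mo, 4, 4, 5, 19, 6, 10, 52 and 19 at 6 mo, and 47, 35, 73, 43, 38, 31, 63 and 46 in the averages. At 12 mo W, Co, Fe, Cu, Al, Pb and DU had 6, 3, 14, 12, 14, 25 and 19, and in the change with time W, Ni, Co, Fe, Al and DU had 11, 4, 12, 9, 10 and 11. Against 1 mo DESeq2 called 89 at 6 mo and 59 at 12 mo.

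With the erythrocyte covariate W, Fe and Pb at 1 mo had 1, 2 and 2, Pb at 6 mo 1, and W, Cu, Pb and DU at 12 mo 0, 1, 4 and 4; averaged Ni, Cu and Pb had 1, 5 and 1; the change with time in Fe, Al, Pb and DU had 4, 5, 7 and 11; 6 against 1 mo had 29. Without libraries under 20000 counts W and DU at 1 mo had 1 and 1, Co at 3 mo 0, and W, Fe, Cu, Al, Pb and DU at 12 mo 0, 4, 4, 2, 3 and 6; averaged Cu and Pb had 0 and 1; the change with time in W, Ni, Co, Cu, Al and DU had 0, 0, 4, 2, 0 and 4.

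With only the 2 groups compared, Fe and Pb at 1 mo, Co at 3 mo, and W and DU at 12 mo had 0, Pb and DU at 3 mo 2 and 6, and Fe at 12 mo 1. Adjusted over all 31 comparisons, Fe and Pb at 1 mo, Co at 3 mo, and W and DU at 12 mo had 0 and Pb at 6 mo 1, because more tests were adjusted for. With a replicate block Co at 3 mo, W at 12 mo and DU at 12 mo had 0, Pb and DU averaged 5 and 3, and the change with time in W 2. Sample numbers did not in general pair the samples: every pair of equal number correlated above 0.1 in 2 of 31 metal and Ta comparisons and in 1 of 51 comparisons of 2 times in 1 metal, so the replicate block is only a check. Those 2 were Al and Pb at 3 mo. At that time replicate 3 had the lowest total in 6 of 9 groups (permutation test, adjusted p = 0.159), so a link of number to handling at 3 mo stays open. In Ta only, 3, 6 and 12 against 1 mo had 6, 0 and 0, with 4 libraries or fewer per time.

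Some miRNAs changed the sign of their fitted log2 change. In Ta only at 3 mo these were miR-1-3p (-0.27), miR-1b (-0.95), miR-146a-5p (1.18), miR-146b-5p (2.01), miR-93-5p (0.56), miR-151-5p (0.87) and miR-16-5p (6.28), the last of which the near-empty Ta library carried; at 6 mo they were miR-503-5p (0.36), miR-24-2-5p (0.18), let-7g-5p (-0.17), miR-126a-5p (0.39), miR-106b-5p (2.90) and miR-144-5p (1.25). In Ta only, edgeR called none of these but miR-16-5p. Among the others the smallest adjusted p was 0.3 (edgeR, miR-146b-5p, 2.01 ± 1.04), so they do not show a reversal. At 3 mo miR-151-5p was at 0.055 with RLE size factors and 0.0017 with DESeq2, which also turned miR-142-5p (0.55) and miR-150-5p (0.77).

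Leaving out 1 library at a time gave these lowest and highest counts, in the order W, Ni, Co, Fe, then Cu, Al, Pb and DU: at 1 mo 0 to 1, 0 to 1, 0 to 2, 0 to 1, 0 to 1, 0 to 1, 0 to 1 and 0 to 1; at 3 mo 0 to 4, 0 to 2, 0 to 4, 0 to 1, 0 to 3, 0 to 1, 0 to 0 and 0 to 4; averaged 0 to 1, 0 to 1, 0 to 4, 1 to 4, 0 to 3, 0 to 1, 1 to 14 and 1 to 14; and for the change with time 0 to 7, 0 to 3, 3 to 8, 0 to 5, 1 to 6, 0 to 4, 10 to 20 and 2 to 9. At 6 mo Fe had 0 to 1, Pb 7 to 11 and the others 0; at 12 mo W, Co, Cu, Al, Pb and DU had 0 to 8, 0 to 1, 0 to 3, 0 to 2, 0 to 4 and 0 to 6. The time comparisons had 126 to 153, 33 to 54 and 28 to 44. Lowest counts came without Ta replicate 3 at 1 mo for Pb, Ta replicate 3 at 3 mo for Co, Ta replicate 4 at 3 mo for Pb averaged, Ta replicate 3 at 6 mo for DU averaged and W replicate 3 at 12 mo for W. The value of miR-30a-3p, 3 mo versus 1 mo over metals, was at most 0.1507 and turned to -1.28 (adjusted p = 0.0151) without Co at 3 mo replicate 3.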

Other observations

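The tests of liver miRNAs by metal and of the X-linked cluster were chosen after the results were seen. Serum miR-122-5p was higher at 12 than at 1 mo in 8 of 8 groups, Ta included, so a rise of this miRNA with age or time may be shared by all implants. Other liver miRNAs did not all follow: miR-192-5p and miR-148a-3p were higher in 5 of 8 groups each and went down to log2 -0.90 and -0.88. The muscle miRNAs miR-1-3p, miR-1b, miR-133a-3p, miR-133b-3p, miR-206-3p and miR-499-5p varied together from library to library within groups, with a median correlation of 0.401 over 132 libraries, above 100% of 9550 random sets of similar abundance (95th percentile 0.153). A candidate explanation is release from muscle, near the implants or at bleeding, that differs between samples and would blur any effect of a metal on these markers. A further hypothesis concerns miR-322, miR-503, miR-351, miR-542 and miR-450, which lie in 1 X-linked cluster: of 12 members tested 9 fell at 3 mo, 4 at 6 mo and 3 at 12 mo against 1 mo, and none rose, by edgeR. Of all 320 miRNAs tested 114, 40 and 22 fell at these times. The median correlation of the members within groups was 0.142, at percentile 95.82 of 7822 random sets (95th percentile 0.138). The members include both strands of the same precursors, and the random sets were matched for abundance only. This narrow pass therefore cannot tell a shared control of the cluster from strands of 1 precursor varying together.

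DESeq2 called 333 miRNAs over the 31 comparisons with Ta, but with metal labels shuffled it called a median of 300.5 (166 to 543 in 20 shuffles, 8 of them with 333 or more), so most of its calls may not be due to the metals. Under edgeR 10.5% of p-values were under 0.05. Shuffled labels gave a median of 7.67% (5.73% to 11.96%), and 1 of 99 shuffles was as large. Small p-values were thus more common than in most shuffles, though not than in all. The 14 calls were reached in 7 of 99 shuffles (median 3, highest 30). Whether Ta itself stood apart from all metals was tested by letting each group be the control: Ta had the most calls at 1 of 4 time points, 1 mo, with 9. At 6 mo the group with most calls was Ni, with 43.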
